A study of Mus musculus with 8 samples.

How the data were processed

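Small RNA libraries were sequenced from 8 samples of mouse bone marrow GMLPs, granulocyte-monocyte-lymphoid progenitors obtained by cell sorting. There were 4 samples from wild-type (WT) mice and 4 from mice with an inducible MLL-ENL transgene (iMLL-ENL). MLL-ENL is a leukaemia fusion protein that joins the N-terminal part of the histone methyltransferase MLL to the elongation factor component ENL. Per the labels' protocols, the cells of both groups spent 3 days in culture with doxycycline, the drug that switches on such transgenes, before total RNA was purified with a kit for low cell numbers and made into libraries with the QIAseq kit for miRNA. The labels do not say whether the replicates came from separate mice, so p-values measure the spread between these samples, which may be technical.

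The authors deposited 1 table with a value per library for each of 964 rows and with the results of their own comparison. The rows analysed here were 328 tRNA genes, 291 snRNA, 279 snoRNA, 56 transcripts with UCSC identifiers, 9 Y RNA and 1 other row, Rnu73b. Rows were classed by name, so Rnu73b is not counted among the snoRNAs here, although GENCODE release M21 gives its gene type as snoRNA. No row analysed here carried a miRNA name, so miRNAs were not analysed here, and the 13 miRNA lists fixed before the data were examined had 0 members to test. The values are reads scaled to a library total of 1000000 (RPM), although the deposited table is labelled as TPM: within each library the values are whole multiples of 1 step that is the same for rows of every class, which leaves no room for division by length. Between 99.79% and 100% of the values of a library were whole multiples within 0.0055 RPM. Taking this step as 1 read, a read was worth 0.108 to 0.169 RPM, which corresponds to 5910000 to 9270000 reads behind the scale of a library. By this estimate the rows analysed here hold 1973055 to 2959969 of these reads per library, and the rest of the scale was not analysed here. A level of 3 reads, the floor below which a value carries little information, lay at 0.32 to 0.51 RPM, and such floors cover counting error only. The authors' deposited table also holds a log2 fold change, a mean log2 CPM, a p-value and a false discovery rate (FDR), per the file headers. This FDR equals a Benjamini-Hochberg adjustment of the authors' p-values over the rows analysed here, with a largest difference of 1.7e-15. Per the submitters' processing notes the genome build was GRCm38. The aligner, counting program, annotation, treatment of multiply mapped reads, use of molecular indexes and any filter are not given in the sources used here. Read lengths were not analysed here, so whole molecules and fragments of a tRNA, snRNA, snoRNA or Y RNA were not told apart.

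The values are scaled and not counts, so the test fixed beforehand for scaled values was used. No count model was run on the reads estimated from the steps, and DESeq2 was not run as an alternative. The smallest value above 0 lay at 1 step in 2 of the 8 libraries and at 2 to 7 steps in the others, so that in those no single value shows what 1 read is worth. The comparison of iMLL-ENL with WT used limma 3.58.1 in R 4.3.3 with statmod 1.5.0 on log2(RPM + 1), with a trended and robust prior variance, two-sided tests, and Benjamini-Hochberg adjustment at 0.05. A row was tested where at least 4 libraries reached 10 RPM, which kept 633 rows and left out 331. Fold changes are on the log2(RPM + 1) scale, which understates the change of low rows. Adjusted p-values below come from this limma fit unless an exact test is named. The prior pools variance over the rows or families fitted together. A limma p-value therefore does not measure the spread of that row or family alone. Many tRNA, snRNA and Y RNA rows are near-identical gene copies whose reads cannot be assigned to 1 copy with certainty. The median correlation between tested copies over the libraries was 0.999 for tRNA-Asp-GTC and for tRNA-His-GTG. Call counts over copies are therefore not independent, and the rows were also summed by name into 67 families, 48 of them tRNA isoacceptors, and tested with the same model but without the filter. Of the 67, 5 held no row past the filter, and 3 of these were called, U4atac and U8 with 1 row each and tRNA-Phe-GAA. The families were defined after seeing the data. Sums of classes were compared with exact two-sided permutation tests over the 70 assignments of libraries to groups, with adjustment over 8 tests, where the smallest p this design allows is 0.0286. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for these tests. For 104 rows the name matched exactly 1 transcript name of GENCODE release M21 on GRCm38, from which coordinates were taken. UCSC identifiers are not paired with gene names in the sources used here.

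The rule for named rows was fixed before the data were examined, and so were the test, the filter and the alternatives listed first below. It takes the 10 rows with the largest rise and the 10 with the largest fall among those past adjusted p 0.05 whose groups did not overlap and whose mean was at least 50 RPM in the higher group, plus the 5 most abundant rows. There were 73 rows eligible among those higher and 50 among those lower. The rule and the test had been written for miRNAs and were applied to the rows analysed here. Planned tests of miRNA lists and of the miRNA shares were not run. On simulated data with the real rows' levels and spreads, 51 of 73 rows changed 2-fold (69.9%) and 62 of 71 rows changed 4-fold (87.3%) were recovered among 641 tested, with 5 false calls of 118 (4.2%). For family sums, 9 of 10 families changed 2-fold and 10 of 10 changed 4-fold were recovered among 67, with 1 false call of 20. The simulation drew each row independently, whereas the real copies of a family vary together. Noise therefore averaged out within the simulated families, and their recovery and false calls do not describe the real family sums. The false calls among rows do not reflect this dependence either.

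The alternatives fixed at that point were TMM scaling of the values (trimming 30% of the ratios and 5% of the levels), centring on the median, quantile normalization, leaving the 5 most abundant rows out of the scaling total, no low filter, a filter of 100 RPM, limma without a trend, pseudocounts of 0.5 and 10, a replicate block, and leaving out each library in turn. Chosen after seeing the data were the family sums, scaling to the total of the rows analysed here, sample quality weights, the class sums and the ratios of isoacceptor families.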

Results

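The series compared the small RNA content of cultured GMLPs from mice with and without the inducible MLL-ENL fusion. The level of the fusion itself was not analysed here. The series held 4 WT and 4 iMLL-ENL libraries. The rows analysed here took 33.4%, 38.5%, 33.4% and 30% of the reads behind the scale in WT replicates 1 to 4, and 28.6%, 26.7%, 26.0% and 29.2% in iMLL-ENL replicates 1 to 4. WT replicate 2 stood apart from the other libraries. Its mean correlation with its own group over the tested rows was 0.908, against 0.955 to 0.968 for the other WT libraries and 0.990 to 0.994 for the iMLL-ENL libraries. The means of the other WT libraries include their correlation with WT replicate 2. Among WT replicates 1, 3 and 4 alone the correlations were 0.984 to 0.99.

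In iMLL-ENL cells, Y RNA and U4 snRNA were higher, and tRNA-His-GTG and tRNA-Arg-TCG were lower. Several tRNA isoacceptors led by tRNA-Gly-CCC and tRNA-Lys-CTT were higher on the scale of the deposited values. None of the tRNA families that rose kept its call under all 5 other scalings. On the scale of the deposited values 183 of the 633 tested rows differed between the groups, 129 higher and 54 lower in iMLL-ENL, and 278 had an unadjusted limma p under 0.05. All 7 tested Y RNA rows rose. Of 198 snoRNA rows 45 rose and 1 fell, of 147 snRNA rows 25 rose and 0 fell, and of 278 tRNA rows 51 rose and 53 fell. Among the 67 families 30 differed, 18 higher and 12 lower. The balance of directions depended on the scaling. The median log2 fold change of the tested rows was 0.31 on the deposited scale, and TMM scaling moved it to -0.08 with 35 rows higher and 129 lower. The calls were 70 higher and 63 lower after quantile normalization, 255 and 29 with the 5 most abundant rows left out of the scaling total, and 251 and 27 after scaling to the total of the rows. For families the same settings gave 3 higher and 19 lower (TMM), 13 and 10 (quantile), 32 and 5 (5 most abundant rows left out) and 34 and 4 (total of the rows). None of the 22 called families with a change under 1 log2 unit was called under all 5 other scalings. Without WT replicate 2, 343 rows (246 higher, 97 lower) and 38 families (23 higher, 15 lower) differed.

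By class, tRNA rows summed to 292631 ± 35840 RPM in WT and 213220 ± 14201 RPM in iMLL-ENL (SD, n = 4), a ratio of 0.729 with no overlap between the groups (exact permutation p = 0.0286, 0.0571 after adjustment over 8 class tests). The sum of all rows was 338084 ± 34805 and 276151 ± 15098 RPM with the same exact p and adjusted p. snoRNA summed to 17936 ± 2944 and 23279 ± 3335 RPM (exact p = 0.0571, adjusted 0.0762) and snRNA to 20188 ± 7521 and 26800 ± 6052 RPM (exact p = 0.257, adjusted 0.294). No class sum passed the adjusted threshold of 0.05. With a smallest exact p of 0.0286, a sum can pass after adjustment over 8 tests only where more sums reach that p than did here. This outcome therefore does not separate sums that differed from sums that did not.

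**Figure D1:**
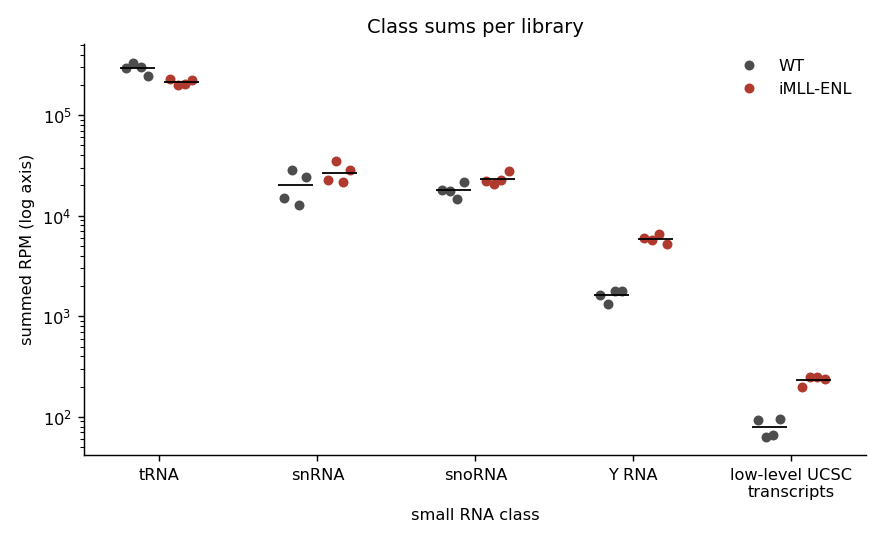
Summed RPM of each small RNA class on a log axis, with a point per library (WT grey, iMLL-ENL red) and a line at each group mean. Y RNA lies between 1337 and 1788 RPM in the WT libraries and between 5195 and 6541 RPM in the iMLL-ENL libraries.

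Y RNAs are short non-coding RNAs bound by the Ro60 protein. Their summed reads, whole or fragments, rose from 1633 ± 209 RPM in WT to 5871 ± 553 RPM in iMLL-ENL (SD, n = 4), a ratio of 3.60. The exact permutation p was 0.0286, the smallest possible, and 0.0571 after adjustment over 8 class tests. The log2 fold change was 1.85 ± 0.14 (SE) with an adjusted p of 1.7e-05 in limma, and 1.45 after TMM scaling. Y_RNA.6-201 rose most among the rows eligible to be named, from 498 ± 48 to 2973 ± 356 RPM (log2 fold change 2.57 ± 0.17, adjusted p = 4.4e-05). Y_RNA.9-201, the most abundant in WT, went from 1047 ± 163 to 2693 ± 279 RPM and Y_RNA.12-201 from 20.96 ± 3.55 to 55.0 ± 8.7 RPM, with adjusted p = 0.0023 for each. The rise of the family and of these 3 rows passed the threshold under all 5 other scalings and without each library in turn.

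**Figure D2:**
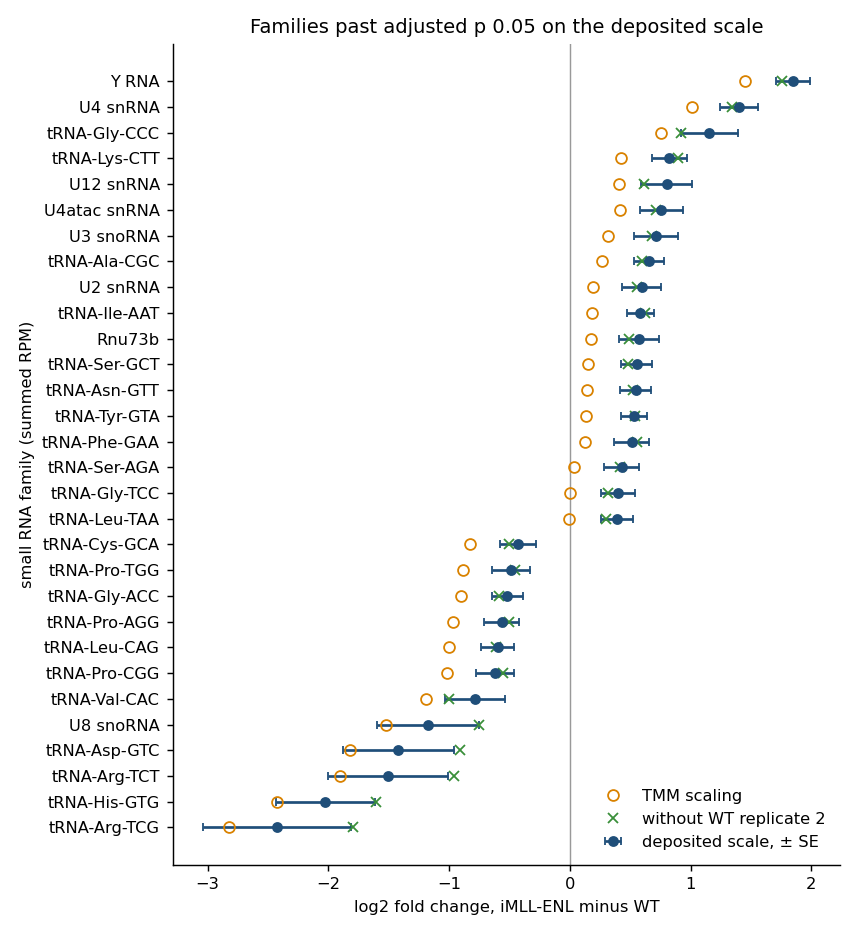
Log2 fold change (iMLL-ENL minus WT) of the 30 families past adjusted p 0.05, on the deposited scale with its SE (filled circles), after TMM scaling (open circles) and without WT replicate 2 (crosses). Y RNA, at 1.85, leads the families that rose and tRNA-Arg-TCG, at -2.43, those that fell, while tRNA-Gly-TCC and tRNA-Leu-TAA move to -0.002 and -0.006 after TMM scaling.

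Among the 48 tRNA isoacceptor families 11 rose, 11 fell and 26 did not pass the test. tRNA-Gly-CCC rose from 7065 ± 2028 to 15204 ± 1401 RPM (log2 fold change 1.16 ± 0.24, adjusted p = 0.0066), with 5 of its 7 copies called. The family was at 0.75 after quantile normalization, where its adjusted p was 0.055, and at 0.92 without WT replicate 2. The median correlation between its copies was 0.738. In the authors' deposited table tRNA317-GlyCCC was at -0.71 and tRNA112-GlyCCC at -0.28, against 0.49 to 0.85 for the remaining copies. The authors' log2 fold changes lay lower than those here by a median of 0.41. tRNA-Lys-CTT rose from 6055 ± 704 to 10691 ± 914 RPM (0.82 ± 0.14, adjusted p = 0.0056), with 9 of 10 copies called, and was at 0.42 after TMM scaling (adjusted p = 0.066) and 0.48 after quantile normalization (0.076). tRNA-Ala-CGC, tRNA-Ile-AAT, tRNA-Ser-GCT, tRNA-Asn-GTT, tRNA-Tyr-GTA, tRNA-Phe-GAA, tRNA-Ser-AGA, tRNA-Gly-TCC and tRNA-Leu-TAA rose by 0.39 to 0.66 on the log2 scale. All 9 lost the call after TMM scaling, where tRNA-Gly-TCC and tRNA-Leu-TAA turned to -0.002 and -0.006. The call of tRNA-Phe-GAA also ended without iMLL-ENL replicate 1 or 4 (adjusted p up to 0.060), that of tRNA-Ser-AGA without WT replicate 1, 3 or 4 or iMLL-ENL replicate 2, 3 or 4 (up to 0.096), that of tRNA-Gly-TCC without any library but WT replicate 4 (up to 0.11), and that of tRNA-Leu-TAA without any library but WT replicate 4 and iMLL-ENL replicate 2 (up to 0.083). tRNA-Gly-GCC, the most abundant family, was at 80600 ± 25098 RPM in WT and 81475 ± 4879 RPM in iMLL-ENL (0.08 ± 0.28, adjusted p = 0.86), and its log2 fold change was -0.33 after TMM scaling (0.44), -0.03 after median centring (0.94) and -0.16 without WT replicate 2 (0.25). Its copies tRNA702-GlyGCC, tRNA706-GlyGCC and tRNA704-GlyGCC, among the 5 most abundant rows, had log2 fold changes of 0.46, 0.48 and 0.50 with adjusted p of 0.19, 0.17 and 0.15, and passed the test after quantile normalization. tRNA704-GlyGCC also passed it without WT replicate 2, with a log2 fold change of 0.28.

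tRNA-His-GTG, the isoacceptor for both histidine codons, fell from 12687 ± 8965 to 2659 ± 392 RPM (log2 fold change -2.02 ± 0.41, adjusted p = 0.0066), with 8 of 10 copies called. tRNA-Arg-TCG fell from 904 ± 957 to 119 ± 31 RPM (-2.43 ± 0.61, adjusted p = 0.015), with all 5 copies called. Both passed the threshold under all 5 other scalings and without each library in turn, and in both the libraries of the groups did not overlap. With a replicate block tRNA-His-GTG kept its call (adjusted p = 0.031) and tRNA-Arg-TCG lost it (adjusted p = 0.058). The 10 named rows that fell were copies of these families and 1 of tRNA-Arg-TCT: tRNA1023-ArgTCG, tRNA961-ArgTCG, tRNA960-ArgTCG, tRNA74-ArgTCG, tRNA628-ArgTCT, tRNA1691-HisGTG, tRNA1432-HisGTG, tRNA747-HisGTG, tRNA751-HisGTG and tRNA291-HisGTG, at log2 fold changes from -3.05 to -2.03. Among these, tRNA961-ArgTCG, tRNA74-ArgTCG and tRNA628-ArgTCT lost the call without WT replicate 1 or without iMLL-ENL replicate 2, 3 or 4, tRNA628-ArgTCT also without iMLL-ENL replicate 1, and tRNA960-ArgTCG without WT replicate 1, with adjusted p up to 0.057. WT replicate 2 held the highest values of these families, 25656 RPM for tRNA-His-GTG and 2327 RPM for tRNA-Arg-TCG. Without it their log2 fold changes were -1.604 (adjusted p = 2.7e-05) and -1.80 (adjusted p = 0.0067).

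tRNA-Asp-GTC fell from 73218 ± 64018 to 21760 ± 1800 RPM (-1.42 ± 0.46, adjusted p = 0.037) and tRNA-Arg-TCT from 545 ± 513 to 147 ± 15 RPM (-1.51 ± 0.50, adjusted p = 0.040). WT replicate 2 was at 168573 and 1310 RPM, and without it the log2 fold changes were -0.91 (adjusted p = 6.7e-08) and -0.96 (adjusted p = 2.4e-07). The SEs there were 0.13 and 0.15. These small adjusted p-values rest in part on the variance pooled over all families once that library was left out. Both calls ended without WT replicate 1 or any 1 iMLL-ENL library, that of tRNA-Arg-TCT also without WT replicate 3, with adjusted p up to 0.086. The call of tRNA-Asp-GTC also ended after quantile normalization (-0.52 ± 0.36, adjusted p = 0.27) and that of tRNA-Arg-TCT after scaling to the total of the rows (-1.22, adjusted p = 0.052). tRNA-Val-CAC, at 61402 ± 15752 and 34697 ± 3871 RPM, had a log2 fold change of -0.79 ± 0.25 (adjusted p = 0.032) that turned to 0.15 after quantile normalization (adjusted p = 0.52), and its call also ended with the 5 most abundant rows left out of the scaling total (adjusted p = 0.24), after scaling to the total of the rows (0.17) and without any 1 library other than WT replicate 2. Its copies tRNA966-ValCAC (-0.80, adjusted p = 0.042) and tRNA284-ValCAC (-0.86, adjusted p = 0.034), also among the 5 most abundant rows, lost their calls without the same libraries and under 4 of the 5 other scalings, all but TMM. All 3 families that read proline codons fell, tRNA-Pro-CGG by 0.62, tRNA-Pro-AGG by 0.57 and tRNA-Pro-TGG by 0.49 on the log2 scale, along with tRNA-Leu-CAG by 0.60, tRNA-Gly-ACC by 0.52 and tRNA-Cys-GCA by 0.43. These 6 lost the call after scaling to the total of the rows and with the 5 most abundant rows left out of the scaling total, and tRNA-Gly-ACC and tRNA-Leu-CAG also after quantile normalization. The call of tRNA-Pro-TGG also ended without WT replicate 1 or 4 or iMLL-ENL replicate 1 or 2 (adjusted p up to 0.094), and that of tRNA-Cys-GCA without WT replicate 1, 3 or 4 or iMLL-ENL replicate 1, 2 or 3 (up to 0.11).

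**Figure D3:**
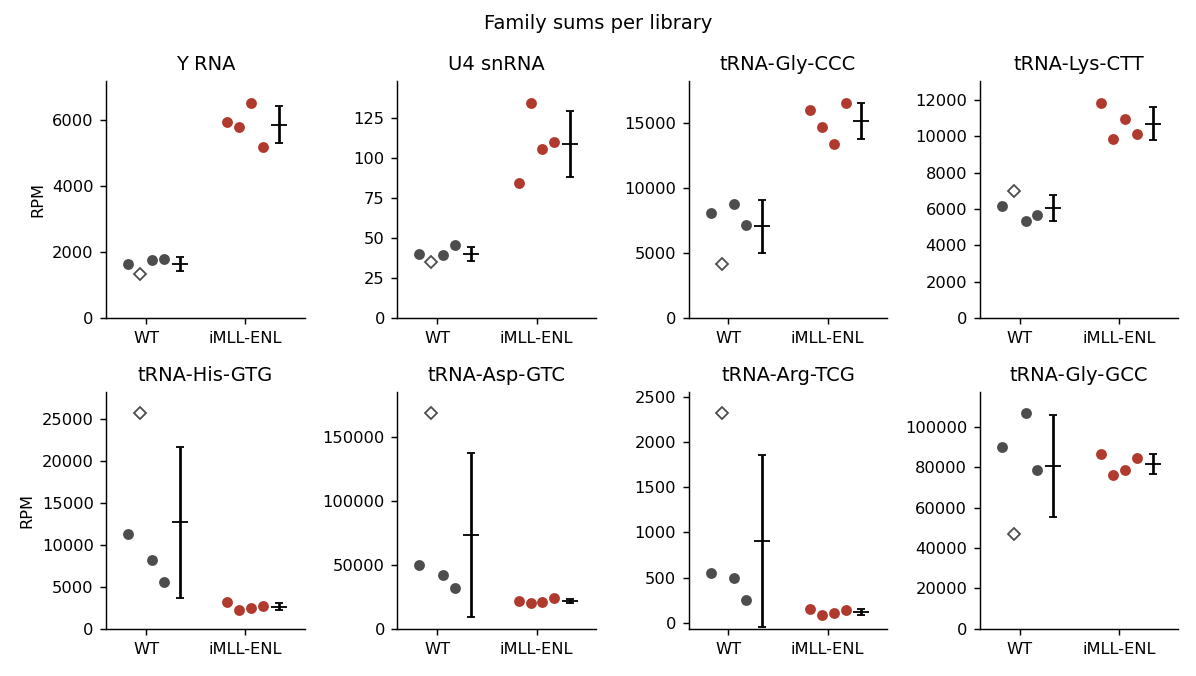
Summed RPM of 8 families, with a point per library (WT grey, iMLL-ENL red, WT replicate 2 an open diamond) and the mean ± SD of each group (n = 4) in black. WT replicate 2 holds the highest value of tRNA-His-GTG, tRNA-Asp-GTC and tRNA-Arg-TCG and the lowest of tRNA-Gly-GCC.

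Among the spliceosomal snRNAs, U4, which pairs with U6 before the spliceosome is activated, rose from 40.2 ± 4.3 to 109 ± 21 RPM (log2 fold change 1.40 ± 0.16, adjusted p = 0.00026, and 1.01 after TMM scaling). U4 passed the threshold under all 5 other scalings and without each library in turn, and so did its named row U4.46-201 (19.0 ± 2.9 to 51.5 ± 8.6 RPM). U12 (0.80 ± 0.21, adjusted p = 0.015) and U4atac (0.76 ± 0.17, adjusted p = 0.011), components of the minor spliceosome, also rose, as did U2 (0.60 ± 0.16, adjusted p = 0.016) with 12 of 19 rows called. U4atac is 1 row at 5.0 ± 1.1 and 9.1 ± 1.3 RPM, below the filter for rows and tested only as a family, and was at 0.35 with a pseudocount of 10. After TMM scaling these 3 were at 0.41 (adjusted p = 0.17), 0.41 (0.0504) and 0.20 (0.41), and U2 also lost the call after quantile normalization (adjusted p = 0.13) and without WT replicate 1 (0.056). U2.12-201 went from 62.8 ± 10.4 to 193 ± 35 RPM (1.599 ± 0.173, adjusted p = 0.0018). The U1 family, at 12674 ± 5188 and 17752 ± 6108 RPM, did not pass the test (0.52 ± 0.34, adjusted p = 0.22) except with the 5 most abundant rows left out of the scaling total (0.84, adjusted p = 0.048), although its rows U1.83-201, U1.199-201 and U1.195-201 rose by 1.45, 1.45 and 1.38 on the log2 scale. Of its 27 tested rows, 4 were called. U1.83-201 lost the call without WT replicate 1, and U1.195-201 without WT replicate 1 or iMLL-ENL replicate 2 or 4. U6 was at 6627 RPM in WT replicate 2 and at 747 to 1187 RPM in the other WT libraries. Its log2 fold change of 0.27 ± 0.62 (adjusted p = 0.77) became 0.96 without that library (adjusted p = 4.1e-06), and that of U5 went from 0.49 ± 0.31 (adjusted p = 0.21) to 0.80 (adjusted p = 0.00016). U5 also passed the test with the 5 most abundant rows left out of the scaling total (0.81, adjusted p = 0.017), after scaling to the total of the rows (0.78, 0.033) and with sample quality weights, as did U6 with these weights (0.81, 0.018). U6 turned to -0.13 after TMM scaling (adjusted p = 0.93) and to -0.09 without WT replicate 3 (0.91).

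The snoRNAs guide chemical modification of ribosomal and spliceosomal RNA. SNORD97.1-201 rose from 410.5 ± 103 to 1318 ± 209 RPM (log2 fold change 1.70 ± 0.21, adjusted p = 0.0022). Snord11-201 (chromosome 1, 59704790 to 59704873, plus strand, GRCm38, in an intron of Nop58) rose from 27.0 ± 8.1 to 70.1 ± 15.0 RPM (1.36 ± 0.22, adjusted p = 0.0075). Both passed the threshold under all 5 other scalings and without each library in turn. The snoRNA row that fell was SNORD30.1-201, named here after its values were seen, from 584 ± 135 to 349 ± 54 RPM (-0.72 ± 0.20, adjusted p = 0.029). Its call ended with the 5 most abundant rows left out of the scaling total (adjusted p = 0.16), after scaling to the total of the rows (0.115) and without WT replicate 1 or iMLL-ENL replicate 1, 2 or 3 (up to 0.081). U3, the box C/D snoRNA needed for 18S ribosomal RNA processing, rose as a family from 476 ± 70 to 792 ± 198 RPM (0.71 ± 0.18, adjusted p = 0.014), with 6 of 10 rows called, and was at 0.31 after TMM scaling (adjusted p = 0.15). Rnu73b rose by 0.57 ± 0.17 on the log2 scale (adjusted p = 0.021), a call that ended after TMM scaling (0.18, adjusted p = 0.39) and without WT replicate 3 or iMLL-ENL replicate 1 or 4. The sums of box C/D (0.38 ± 0.18, adjusted p = 0.11) and box H/ACA snoRNAs (0.34 ± 0.19, adjusted p = 0.15) did not pass the test on the deposited scale. Both passed it with the 5 most abundant rows left out of the scaling total (0.70, adjusted p = 0.046, and 0.66, 0.025) and after scaling to the total of the rows (0.67, 0.033, and 0.63, 0.029). After TMM scaling they were at -0.02 (0.94) and -0.06 (0.84), and box H/ACA was at -0.02 after quantile normalization (0.97). The box C/D sum also passed the test without WT replicate 2 (0.37, adjusted p = 0.015) and with sample quality weights (0.34, 0.045). The row named U8, below the filter for rows and tested only as a family, fell from 15.2 ± 11.6 to 5.3 ± 2.0 RPM (-1.18 ± 0.42, adjusted p = 0.049), with overlapping groups and a call that ended without 6 of the 8 libraries, all but WT replicates 2 and 3, with a pseudocount of 10 (-0.63, adjusted p = 0.097) and in limma without a trend (0.058). Without WT replicate 2 it was at -0.75. Snord118-201, the gene of U8 (chromosome 11, 69073427 to 69073561, plus strand), was tested as a row, at 579 ± 68 and 560 ± 145 RPM (-0.07 ± 0.20, adjusted p = 0.81). Its log2 fold change was above 0 with the 5 most abundant rows left out of the scaling total (0.24), after scaling to the total of the rows (0.21), with sample quality weights (0.04) and without iMLL-ENL replicate 2 (0.07), and passed the test in no setting. Both U8 rows were chosen after their values were seen.

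The 5 most abundant rows together took 13.96% ± 4.41 of the sum of all rows in WT and 15.9% ± 0.7 in iMLL-ENL (SD, n = 4, exact permutation p = 0.77, adjusted 0.77). WT replicate 2 was at 7.37%, and without it the difference changed sign to -0.30 percentage points.

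A total of 159 rows in the authors' deposited table had an FDR under 0.05, 44 higher and 115 lower in iMLL-ENL. Of the 633 rows tested here, 93 were called in the authors' deposited table, and 67 of these were also called here, all in the same direction, against 90 after TMM scaling here. The other 26 were not called here, and 66 of the authors' calls lay in rows not tested here. The authors' lower calls included many U6 rows, such as U6.6-201 (-2.79, FDR 0.0092), while U6.112-201 was called higher. Of the 87 U6 rows tested here, 5 were called higher and 0 lower. The U6 family was at 6627 RPM in WT replicate 2 and at 747 to 1187 RPM in the other WT libraries. It was at 1671 to 2082 RPM in the iMLL-ENL libraries, and its log2 fold change here was 0.96 without WT replicate 2. Whether the authors' lower U6 calls rest on that library was not tested. No tRNA-Gly-CCC or tRNA-Lys-CTT row was called by the authors, with lowest FDRs of 0.11 and 0.34. The log2 fold changes of the authors' deposited table correlated with those computed here at r = 0.977 across rows, which are not independent replicates, and lay lower by a median of 0.41, against 0.02 after TMM scaling here.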

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

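All tests in this part were chosen after the result was seen. In each group of 4 libraries, 1 library was taken as far from the rest where its gap to the nearest other exceeded the 95% limit of Dixon's ratio. This held for 21 of 198 groups examined, against about 9.9 by chance at 1 in 20, and 15 of the 21 were WT replicate 2. The groups overlap, since named rows and class sums share reads with the families, so 1 deviation can count more than once. The chance figure also assumes that RPM values spread normally within a group.

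WT replicate 2 was far above the other WT libraries for tRNA-Asp-GTC (168573 against 31830 to 50309 RPM), tRNA-Arg-TCG (2327 against 246 to 549), tRNA-Arg-TCT (1310 against 218 to 342), tRNA-Arg-ACG (763 against 110.0 to 171) and tRNA-Arg-CCG (288 against 101 to 116). The same held for the rows tRNA1023-ArgTCG (841 RPM), tRNA961-ArgTCG (618 RPM), tRNA74-ArgTCG (399 RPM) and tRNA628-ArgTCT (678 RPM). It was also above them for U6 (6627 against 747 to 1187 RPM), U6atac (136 against 47.9 to 49.9), tRNA-Ile-TAT (63.3 against 21.3 to 25.2) and tRNA-Val-TAC (439 against 269.7 to 296). It was below them for tRNA-Val-AAC (11501 against 22110 to 23833 RPM) and for the share of the 5 most abundant rows (7.37% against 15.7% to 16.4%).

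The fall of tRNA-His-GTG, tRNA-Asp-GTC, tRNA-Arg-TCG and tRNA-Arg-TCT in iMLL-ENL was weighed against this library and against the scaling. WT replicate 2 alone is argued against, since without it the median log2 fold change of the 4 families was -1.28, against -1.76 with it, and all 4 passed the threshold. The scaling is argued against for tRNA-His-GTG and tRNA-Arg-TCG, whose value closest to 0 under 5 other scalings was -1.70 ± 0.32, but could account for the call of tRNA-Asp-GTC, at -0.52 ± 0.36 after quantile normalization (adjusted p = 0.27), and stays open for tRNA-Arg-TCT, whose values reached -1.19 ± 0.42 and whose call ended at an adjusted p of 0.052 after scaling to the total of the rows. Whether the group difference lies on the same axis as the deviation of WT replicate 2 cannot be told apart: across 48 tRNA families the difference of WT replicates 2 and 1 ran against that of iMLL-ENL and WT replicates 3 and 4 (r = -0.34, permutation p = 0.018, families not being independent), but across the 44 others r was 0.07 (p = 0.64). The genotype stays open as an explanation.

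iMLL-ENL replicate 4 was above the others of its group for box H/ACA snoRNAs (2726 against 1879 to 1988 RPM), U3 (1084 against 648 to 720.2) and scaRNAs (377 against 284 to 296), and below them for Y_RNA.6-201 (2445 against 3085 to 3212 RPM). WT replicate 4 was above the other WT libraries for U3 (581 against 435 to 446 RPM), and iMLL-ENL replicate 1 above its group for tRNA-Gly-ACC (25.3 against 21.9 to 22.4 RPM).

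The rise of Y RNA was weighed in the same way. Scaling is argued against by a lowest log2 fold change of 1.45 ± 0.17 (adjusted p = 0.00059) over 5 other scalings, and a single library by values of 1.76 to 1.91 with each library left out (adjusted p at most 0.00021). A different mix of cells in the cultures cannot be told apart from a change within the cells, since 0 members of the marker lists were among the rows. The genotype stays open beside it, and a rise of Y RNA in cells with MLL-ENL is a hypothesis found and tested on the same data.

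Of the 35 ways to split the 8 libraries into groups of 4, only the real one gave as many rows (183, with 0 as the highest of the others) or as many families (30, with 0 as the highest of the others), 1 of 35 in each case. This share is the smallest that 35 splits allow, and the families were defined after seeing the data. It argues against a chance arrangement of these 8 libraries for these counts. It cannot speak to a difference between the sources of the cells other than genotype, since the replicates may be technical.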

How the results depend on the processing

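Family, class and ratio results, scaling to the total of the rows and sample quality weights were chosen after seeing the data. Rows called (183, 129 higher and 54 lower) became 282 (230 higher) with no low filter and 120 (66 higher) with a filter of 100 RPM, where other numbers of rows were tested. They became 284 (255 and 29) with the 5 most abundant rows left out of the scaling total, 278 (251 and 27) after scaling to the total of the rows, and 457 (322 and 135) with sample quality weights, whose estimation stopped before convergence. With TMM scaling 35 were higher and 129 lower, and with quantile normalization 70 were higher. The cause was not tested. Leaving out 1 library gave 59 to 343 rows, 46 to 246 higher and 13 to 97 lower, with the fewest without WT replicate 1 and the most without WT replicate 2. Median centring, limma without a trend and pseudocounts of 0.5 and 10 gave 162 to 185 rows. Of 30 families, 18 higher and 12 lower, TMM scaling gave 3 and 19, leaving out the 5 most abundant rows 32 and 5, and scaling to the total of the rows 34 and 4. Leaving out 1 library gave 20 to 38 families, 6 to 15 of them lower. The log2 fold change turned to -0.002 for tRNA-Gly-TCC and -0.006 for tRNA-Leu-TAA (TMM) and to 0.153 for tRNA-Val-CAC (quantile). Of the 22 named rows called, 20 were called under all 5 scalings and 14 without each library in turn. The deviations of same-numbered libraries from their group means correlated at 0.389, 0.286, -0.133 and 0.42 for numbers 1 to 4, with a mean of -0.073 for other numbers, and 6 of 8 libraries correlated best with their own number. This hints at a link for numbers 1, 2 and 4. The numbers were not taken to pair the libraries, since number 3 ran the other way and the labels state no pairing. A replicate block gave 193 rows (151 higher, 42 lower) and 24 families (17 higher, 7 lower), without the calls of tRNA-Arg-TCG, tRNA-Asp-GTC, tRNA-Arg-TCT, tRNA-Pro-TGG, tRNA-Gly-TCC and U8. As a block in the exact tests, where p cannot go below 0.13, the differences of -61933 RPM for the sum of all rows, -79411 for tRNA, 4238 for Y RNA and 155 for low-level UCSC transcripts had that p. With 1 library left out these differences were -74623 to -46476 for all rows and -95144 to -66142 for tRNA (exact p up to 0.0571), 3983 to 9414 for snRNA (6612 with all libraries, exact p from 0.171 to 0.457), and 3735 to 6626 for snoRNA and 906 to 1560 for UCSC transcripts (exact p from 0.0286 without WT replicate 4 for both). The share of the 5 most abundant rows differed by 1.90 percentage points, by -0.30 to 2.72 with 1 library left out, by 1.43 for the most abundant row (exact p = 0.0286) and by -1.38 for the 20 most abundant (exact p = 0.94). The set tests, miRNA shares and DESeq2 test that had been planned were not run. At 0.108 to 0.169 RPM per read, rows near 1 RPM rest on about 10 reads or fewer.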

Other observations

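All tests in this part were chosen after the data were seen. Ratios of tRNA isoacceptors within a library are unchanged by a scaling factor per library, but not by quantile normalization. Each of the 3 ratios set a called family whose groups did not overlap over an uncalled family of the same amino acid. A small exact p was therefore likely in advance, and the adjustment covers only these 3 of the possible pairs. The uncalled families were no fixed reference, since of 8 tested tRNA-Lys-TTT copies 2 were called higher and 2 lower. The log2 ratio of tRNA-Gly-CCC to tRNA-Gly-GCC lay between -3.60 and -3.45 in the 4 WT libraries, WT replicate 2 included, and between -2.55 and -2.35 in the 4 iMLL-ENL libraries. The difference was 1.08, with SDs of 0.07 and 0.09 (exact permutation p = 0.0286, also after adjustment over 3 ratios). The log2 ratio of tRNA-Lys-CTT to tRNA-Lys-TTT was 0.83 ± 0.06 in WT and 1.32 ± 0.12 in iMLL-ENL, and that of tRNA-Arg-TCG to tRNA-Arg-CCT was 1.24 ± 1.43 and -1.17 ± 0.23, with the same exact p and adjusted p for each (SD, n = 4). Without WT replicate 2 the last difference went from -2.41 to -1.74, and without any 1 iMLL-ENL library its exact p was 0.0571. After quantile normalization of the families the differences were 0.50 for the glycine ratio (exact p = 0.0571), 0.25 for the lysine ratio (0.371) and -2.35 for the arginine ratio (0.0286), and none passed the test after adjustment over 3 ratios (adjusted p = 0.0857, 0.371 and 0.0857).

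A group of 54 transcripts with UCSC identifiers and a mean of 1.67 to 4.59 RPM, too low for the filter, was higher in iMLL-ENL. All 54 had the higher mean there, and in 49 the groups did not overlap in that direction. By chance this would hold for 1.43% of rows, but only without an overall shift. Low rows of other classes also rose, as given below, and the share of those rows with groups apart was not computed. Their sum was 78.9 ± 16.6 RPM in WT and 234 ± 25 RPM in iMLL-ENL (SD, n = 4, exact permutation p = 0.0286, 0.0571 after adjustment over 8 class tests), and 19 had an FDR under 0.05 in the authors' deposited table. A rise of all rows near the floor could account for part of this, since 85 rows of other classes in the same range of means had a median log2 ratio of 0.68. As the whole explanation it is argued against, since the median of the UCSC rows was 1.42 and the log2 ratio of their sum to the sum of the other 85 was higher by 0.99 in iMLL-ENL (exact permutation p = 0.0286), at -2.10 to -1.04 in WT and -0.60 to -0.21 in iMLL-ENL. The difference of 0.99 was not computed without WT replicate 2, so its size may depend on that library. Reads shared between the rows stay open, as the median correlation of their deviations within groups was 0.33, so that the 54 are not independent, and the genotype stays open beside it.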
